A study of Mus musculus with 14 samples.

How the data were processed

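The samples were spleen RNA of AcB55 mice (6 arrays) and AcB61 mice (8 arrays), each hybridised with spleen RNA of A/J mice on a cDNA array with 2 channels. Per the labels' protocols, tissue was frozen, RNA was extracted with TRIzol, and total or poly(A) RNA was copied into cDNA labelled with Cy3 or Cy5. Per the labels, images were taken with a ScanArray scanner, quantified with QuantArray 3.0 and imported into GeneSpring together with quality information on the spots. The label text breaks off where a dye swap and the handling of intensity are named, so the normalization is not given in the sources used here. The dye of each channel, the log base and the centring are likewise not given.

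The deposited table holds a log2 ratio of the channels for each feature and array. It is read as such because its values are positive and negative decimals with medians per array between -0.0205 and 0.0087. Base 2 was taken, and another base would scale every value by a common factor without moving a sign or a test against 0, although it would move the counts at 1.5-fold. The strain is named as channel 1 and A/J as channel 2 of every array, so positive values were read as higher in the strain. Within strains the arrays correlated over all features with a median r of 0.546 in AcB55 (0.403 to 0.748) and 0.449 in AcB61 (-0.089 to 0.833), and between strains with 0.207 (-0.005 to 0.521). Signal and background intensities were not used here, so the strength of each spot is unknown.

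The table lists 15247 features, of which 14612 had a value on at least 1 array, 12970 on all arrays and 635 on none. Gene names came from the platform annotation of the repository. Of the measured probes, 7849 had 1 gene symbol, 356 had several and 6407 had none listed, and probes of the last 2 kinds stayed without a name. The gene identifiers of 7830 probes were found in the reference gene table, and 0 symbols needed an update. Names were checked on the 996 genes with exactly 2 probes: the strain means of both probes correlated at 0.481 in AcB55 and 0.497 in AcB61, against at most 0.074 and 0.091 in 200 random pairings. Probes of a gene were averaged on each array, and 22, 20 and 6 of 1246 genes with more than 1 probe had probes called in opposite directions in AcB55, in AcB61 and between the strains. The medians lay within 0.1 of 0, so the values were used as deposited, with no further centring. A feature was tested when at least 3 arrays of each strain had a value, which left 13045 features and 6286 genes.

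R 4.3.3 with limma 3.58.1 was used for the tests, with lmFit, a mean per strain over all 14 arrays, no covariate and eBayes. The mean log2 ratio of each strain was tested against 0, and AcB61 minus AcB55 as the difference of the means. All p-values are two-sided, with the adjustment of Benjamini and Hochberg over all features of a comparison and a threshold of 0.05 on the adjusted p. No A/J sample was hybridised against another, so the test against 0 leaves out the spread among A/J mice. Whether arrays share an animal or an RNA pool is not given, and each array was counted as a replicate. Figures and checks used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

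The design, the alternatives, the rule for named genes and 23 gene lists were fixed before the data were examined. Named genes are, for each comparison, the 10 largest changes in each direction among single-symbol genes past the threshold. They needed the same sign on every array of the strain or, between strains, ranges that do not overlap. To these were added up to 4 members of each list past the threshold with the largest change, and Pklr, Vnn1, Vnn3, Hba-a1, Hbb-b1, Alas2, Tfrc and Hmox1 where measured. Genes named outside the rule were chosen after their values were seen. They are Ltf and Cpa1, from lists with few measured genes, values that did not pass of genes named for the other strain, and all genes named only in the closing part. For red cells and their precursors the lists were globins and haem synthesis, red cell membrane, erythroid regulators, and red cell enzymes and antioxidants. For other cells and tissues they were macrophages, B cells, plasma cells, T and NK cells, granulocytes, megakaryocytes and platelets, exocrine and endocrine pancreas, and stroma with vessels and fat. For immune responses they were MHC class II, MHC class I, interferon response, and malaria response and candidate genes. The others were glycolysis, cell cycle and DNA replication, iron handling, chaperones, cytosolic ribosomal proteins, proteasome, and oxidative phosphorylation. Of these, 14 had at least 5 measured members and are described as groups. The B cell list was measured by Blnk alone, that of T and NK cells by Satb1 and that of the pancreas by Cpa1. Lists were tested with cameraPR of limma with a correlation between genes of 0.01, adjusted over the lists of a comparison. Each list was set against all other tested features, which include 6759 without a single gene name. Beside it stand camera with an estimated correlation, fry, and exact sign-flip or exact permutation tests of the list means per array.

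Alternatives were centring each array, scaling all arrays to a common spread, testing every probe and filters on missing values. Arrays whose numbers in the titles share their leading digits were taken as a series, which no label states, and the series was fitted as a random block. Further alternatives were leaving out the 2 AcB55 arrays with b in their titles, array weights, a robust variance prior, fits within a strain, a 1.5-fold threshold and leaving out each array in turn. Added after the data were seen were the first residual component as a covariate and a fit without the 2 AcB55 arrays highest in S100a9, replicates 1 and 2. The test was checked on simulated data with 100 features changed per size. For AcB55 it recovered 97% of changes of 0.5 and 99% of changes of 1 on the log2 scale, for AcB61 99% and 100%, and between strains 72% and 98%, with 4.39%, 6.57% and 3.95% of calls false. A list shifted in the simulation was found in all 3 comparisons, and 0 of the 22 other lists were called. Features were simulated independently, with no correlation between genes and no shared A/J sample. These rates therefore do not cover real lists, where the estimated correlation was for example 0.207 for the cell cycle. Overlap between strains was set against 20 simulations with and without a shared A/J sample. Gene order on chromosomes was taken from the RefSeq annotation of GRCm38.p6, and no coordinates are given.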

Results

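RNA from the spleens of AcB55 and AcB61 mice was measured on 14 cDNA arrays with 2 channels each, with spleen RNA of A/J mice in the other channel of every array. AcB55 and AcB61 are recombinant congenic strains, inbred lines that carry segments of C57BL/6 on a background of A/J, and the series is titled with resistance to malaria. There were 6 arrays of AcB55 and 8 of AcB61, and A/J was never measured against A/J. The labels do not say whether the mice were infected, their sex, or which arrays shared a mouse. Each array gave a value for 14197 to 14588 features, and 13045 features, 6286 of them single named genes, could be tested. The number of arrays limits the precision. Values below are mean log2 ratios of the strain to A/J ± SD over arrays, with n = 6 for AcB55 and n = 8 for AcB61 unless another n is given. Values per array are named by strain and by the order of deposit (replicate 1 and so on). The direction is likely the strain over A/J, on the basis that the labels name the strain as the first and A/J as the second channel of all 14 arrays. The dyes are not given per array, and the lowest correlation between any pair of arrays was -0.089. A p-value here measures the spread between arrays, which may be technical, and leaves out the spread among A/J mice.

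The first comparison asked which spleen transcripts of AcB55 differed from A/J, the main parent of the strain. Genes of dividing cells and of red cell precursors were higher in AcB55. Mki67 (1.83 ± 0.25), the marker of cycling cells, rose the most, and with it Ccna2 (1.04 ± 0.094), which encodes cyclin A2. Slc4a1 (1.28 ± 0.31, n = 5), the anion exchanger of the red cell membrane, and Rhd (1.13 ± 0.31), its Rh blood group protein, rose as well. H2-Eb1 (-1.31 ± 0.15), a chain of MHC class II, B2m (-0.84 ± 0.33), the light chain of MHC class I, and Blnk (-1.07 ± 0.30), the linker protein of the B cell receptor, were lower. Of the 2 measured MHC class II genes the other rose, of the 4 of class I no other passed, and neither list shifted (adjusted p = 0.0868 and 0.332). The cytosolic ribosomal protein list shifted downward, with 39 of 61 genes lower (adjusted p = 1.09e-15, and 0.0371 with an estimated correlation). The other genes of the 10 largest increases were Tmcc2 (1.43 ± 0.33), the anion exchanger Slc4a2 (1.22 ± 0.37) and Prex2 (1.25 ± 0.62, n = 5), which activates Rac GTPases. Gm5088 (1.16 ± 0.42), Nxpe2 (1.15 ± 0.13) and the poly(A)-binding protein Pabpc4 (1.04 ± 0.18) completed them. The 10 largest decreases also held Shisa5 (-1.40 ± 0.30, n = 5), Cpt2 (-1.38 ± 0.21), a mitochondrial enzyme of fatty acid oxidation, the membrane protein Snn (-1.19 ± 0.28) and Nemp1 (-1.16 ± 0.23) of the nuclear envelope. Mfge8 (-1.15 ± 0.27), which bridges phagocytes to dying cells, Il16 (-1.11 ± 0.19, n = 5), Nfkbia (-1.04 ± 0.19), the inhibitor of NF-kappa-B, and the phosphatase Lhpp (-1.03 ± 0.21) were the others. Adjusted p for these 20 genes lay between 1.9e-10 for Mki67 and 6.23e-05 for Gm5088. Each had the same sign on every AcB55 array that measured it, which the rule for named genes required.

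Of the 45 measured genes of the cell cycle and DNA replication list, 36 rose, 1 fell and 8 did not pass the test, with 39 higher and 2 lower when adjusted over the list alone (median 0.53, adjusted p = 2.28e-30, and 0.0371 with an estimated correlation). Among them were Nusap1 (1.00 ± 0.073), a spindle protein, and Rrm2 (0.99 ± 0.11), a subunit of ribonucleotide reductase. Of 15 genes of globins and haem synthesis, 11 rose, 0 fell and 4 did not pass, with 11 adjusted over the list alone (median 0.40, adjusted p = 8.89e-10, and 0.0371 with an estimated correlation). Examples were Abcb10 (0.85 ± 0.14), a mitochondrial transporter of red cell precursors, and the haem synthesis enzymes Ppox (0.71 ± 0.32), Uros (0.70 ± 0.21) and Urod (0.58 ± 0.23). Alas2 (0.41 ± 0.33), the first enzyme of haem synthesis in red cell precursors, also rose (adjusted p = 0.00611), with values of 0.665 to 0.744 on replicates 1, 2 and 5 and 0.083 to 0.14 on replicates 3, 4 and 6. Without replicates 1 and 2, a setting chosen after the values per array were seen, its mean of 0.25 was no longer past the threshold (adjusted p = 0.146). Hba-a1 (-0.013 ± 0.15), adult alpha globin, did not pass the test (adjusted p = 0.931), on spots whose spread was far below that of other genes. Of 15 red cell enzymes and antioxidants, 9 rose, 1 fell and 5 did not pass, with 9 higher and 1 lower when adjusted over the list alone (median 0.42, adjusted p = 3.03e-05, and 0.0467 with an estimated correlation). Catalase, Cat (0.82 ± 0.11), and Bpgm (0.81 ± 0.37), which makes 2,3-bisphosphoglycerate in red cells, were the largest of these, followed by Gclc (0.61 ± 0.18) of glutathione synthesis and the carbonic anhydrase Car1 (0.61 ± 0.25). Of 8 red cell membrane genes, 3 rose, 1 fell and 4 did not pass, the same counts as when adjusted over the list alone (median 0.18, adjusted p = 0.00144), but the call was lost at adjusted p = 0.199 with an estimated correlation. Besides Slc4a1 and Rhd these were Bsg (0.46 ± 0.13), which rose, and Ermap (-0.24 ± 0.12), which fell. Of 7 erythroid regulators, 4 rose, 0 fell and 3 did not pass, with 5 higher when adjusted over the list alone (median 0.31, adjusted p = 0.00055, but adjusted p = 0.0595 with an estimated correlation). They were Bcl2l1 (0.83 ± 0.28), which protects red cell precursors from apoptosis, the transferrin receptor Tfrc (0.68 ± 0.20), Bnip3l (0.39 ± 0.18), needed to clear mitochondria, and Foxo3 (0.31 ± 0.25).

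Cytosolic ribosomal protein genes were the largest group that fell in AcB55: 39 of 61 fell, 0 rose and 22 did not pass, with 44 lower and 1 higher when adjusted over the list alone (median -0.33, adjusted p = 1.09e-15, and 0.0371 with an estimated correlation). Rpl38 (-0.75 ± 0.32), Rps13 (-0.65 ± 0.15), Rps20 (-0.63 ± 0.34) and Rpl36 (-0.63 ± 0.36) had the largest decreases. Of 13 macrophage genes, 8 fell, 1 rose and 4 did not pass, with 8 lower and 2 higher when adjusted over the list alone (median -0.26, adjusted p = 0.0152, but adjusted p = 0.202 with an estimated correlation). The complement genes C1qa (-0.63 ± 0.46) and C1qc (-0.42 ± 0.15) and the protease Ctsl (-0.41 ± 0.071) fell, whereas the protease Ctsb (0.44 ± 0.084) rose. Of 15 genes of stroma, vessels and fat, 6 fell, 0 rose and 9 did not pass, with 7 adjusted over the list alone (median -0.14, adjusted p = 0.00585, but adjusted p = 0.148 with an estimated correlation). Among them were the matrix proteoglycans Dcn (-0.60 ± 0.31) and Bgn (-0.53 ± 0.25) and the endothelial genes Pecam1 (-0.39 ± 0.14, n = 5) and Cdh5 (-0.28 ± 0.14). Of 7 interferon response genes, 3 fell, 1 rose and 3 did not pass, as when adjusted over the list alone (median -0.11, adjusted p = 0.0163, but adjusted p = 0.506 with an estimated correlation). Bst2 (-0.71 ± 0.23), Irf1 (-0.69 ± 0.21) and Stat2 (-0.29 ± 0.045) fell and the GTPase Igtp (0.33 ± 0.15) rose. Of 51 genes of oxidative phosphorylation, 7 fell, 3 rose and 41 did not pass, with 5 lower and 3 higher when adjusted over the list alone (median -0.12, adjusted p = 0.043, but adjusted p = 0.537 with an estimated correlation). Cox7a2l (-0.67 ± 0.17), Ndufv3 (-0.39 ± 0.23) and Ndufa7 (-0.38 ± 0.19) fell and Atp5a1 (0.44 ± 0.24) rose. The list of oxidative phosphorylation was no longer past the threshold without AcB55 replicate 3, 4, 5 or 6 (adjusted p = 0.0773, 0.065, 0.0769 and 0.313).

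Lists with no shift in AcB55 held single genes that changed. Of 8 iron handling genes, 2 rose, 0 fell and 6 did not pass, as when adjusted over the list alone (adjusted p = 0.0704), namely the haem-degrading enzyme Hmox1 (0.88 ± 0.27, n = 5) and the siderophore-binding protein Lcn2 (0.65 ± 0.82). Of 23 chaperones, 7 rose, 4 fell and 12 did not pass, with 9 higher and 4 lower when adjusted over the list alone (adjusted p = 0.0906). Hsp90aa1 (0.70 ± 0.11), Hspa8 (0.40 ± 0.12) and Dnajb1 (0.39 ± 0.13) rose, and Pdia6 (-0.42 ± 0.19) of the endoplasmic reticulum fell. Of 11 glycolysis genes, 1 rose, 1 fell and 9 did not pass, with 1 higher and 3 lower when adjusted over the list alone (adjusted p = 0.506). The muscle isoform of phosphofructokinase, Pfkm (0.25 ± 0.14), rose and the pyruvate kinase Pkm (-0.69 ± 0.18) fell. Of 33 proteasome genes, 2 rose, 2 fell and 29 did not pass, as when adjusted over the list alone (adjusted p = 0.997, with a median of 0.016 and a mean of -0.015). Psmd1 (0.35 ± 0.15) and Psmd2 (0.27 ± 0.20) rose, and the activator subunit Psme1 (-0.73 ± 0.23) and the assembly factor Pomp (-0.33 ± 0.15) fell. Lists with fewer than 5 measured genes are given by gene. The plasma cell genes Xbp1 (-1.01 ± 0.25, n = 5) and Creld2 (-0.35 ± 0.14), Satb1 (-0.18 ± 0.14) of T cells and the cytokine Il18 (-0.42 ± 0.19, n = 5) fell, and H2-DMa (0.31 ± 0.15), which loads peptides on MHC class II, rose. Of the granulocyte genes S100a9 (0.59 ± 0.89), Ltf (0.46 ± 0.70) and Hdc (-0.022 ± 0.054), the platelet genes Ppbp (-0.32 ± 0.55) and Selp (0.0023 ± 0.10), and the pancreatic enzyme Cpa1 (-1.42 ± 2.29, n = 5), 0 passed the test, although 2 of the granulocyte genes were higher and Cpa1 was lower when adjusted over the list alone. S100a9 and Lcn2 read 1.48 and 1.47 on replicate 1 and 1.94 and 1.89 on replicate 2, against -0.096 to 0.26 and -0.0086 to 0.29 on the other 4 arrays. The same 2 arrays had the highest list means of haem synthesis (0.59 on each, against 0.25 to 0.34 on the others), the cell cycle (0.678 and 0.673 against 0.381 to 0.490), red cell enzymes (0.516 and 0.511 against 0.142 to 0.283) and erythroid regulators (0.544 and 0.435 against 0.207 to 0.382). They were also highest for the ribosomal protein, proteasome and oxidative phosphorylation lists.

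In total 2695 features passed the test in AcB55, 1274 higher and 1421 lower, of which 705 and 976 were named genes. At least 1.5-fold changes were 330 of them. The list means of the cell cycle, haem synthesis, red cell enzymes and ribosomal proteins each had a single sign on all 6 arrays, which gives an exact two-sided sign-flip p of 0.0312, the smallest that 6 arrays allow and not past the threshold once adjusted over the lists (0.0505). Pklr, Vnn1, Vnn3 and Hbb-b1 were not analysed here, since no tested feature carried their name alone. The calls of Foxo3, Lcn2, Pfkm, Psmd2 and Satb1 were lost without replicate 1 (adjusted p = 0.0917, 0.147, 0.0833, 0.109 and 0.0602), and those of Foxo3, Lcn2, Pfkm and Satb1 without replicate 2 (0.0928, 0.163, 0.0512 and 0.0974). So were those of Pfkm, Psmd2 and Satb1 without replicate 5 (0.0634, 0.0798 and 0.105), that of Psmd2 without replicate 4 (0.0852) and those of Psmd2 and Satb1 without replicate 6 (0.0718 and 0.0978). Without replicates 1 and 2 together, calls were also lost for Igtp, Ermap, Cdh5 and Pecam1 (0.123, 0.07, 0.0697 and 0.0526), and without the 2 arrays marked b in their titles, replicates 3 and 4, for Atp5a1, Igtp and C1qc (0.1, 0.0725 and 0.0774).

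**Figure D1:**
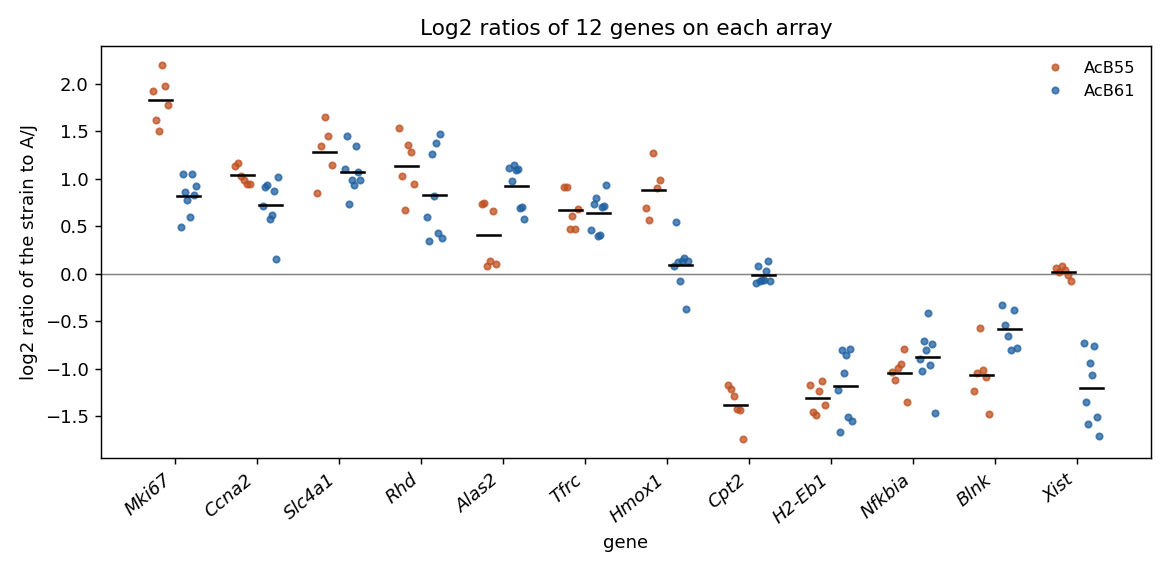
Log2 ratio of the strain to A/J (vertical axis) of 12 genes on each array, with AcB55 in orange, AcB61 in blue, a point per array and a black bar at the mean of each strain. On every array that measured them, Mki67, Slc4a1 and Rhd lie above 0 and H2-Eb1, Nfkbia and Blnk below 0, and Xist and Cpt2 are low in a single strain.

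The second comparison asked the same of AcB61. Genes of red cell precursors and of dividing cells were again higher than in A/J, with Slc4a1 (1.07 ± 0.23), Alas2 (0.92 ± 0.23) and Alad (0.96 ± 0.31), the second enzyme of haem synthesis, among the 10 largest increases. The granulocyte protein S100a9 (1.10 ± 0.36) and Lcn2 (0.98 ± 0.44), which granulocytes also make, rose on every AcB61 array. Of the 3 measured genes of the granulocyte list, however, Hdc fell and 1 did not pass, and the list did not shift (adjusted p = 0.594). H2-Eb1 (-1.18 ± 0.36), B2m (-0.65 ± 0.26) and Blnk (-0.58 ± 0.20, n = 6) fell, as did Xist (-1.20 ± 0.38), the RNA that silences an X chromosome in female cells. The sex of the mice is not given, so unmatched sex cannot be told apart from the strain, here or in AcB61 against AcB55. The proteasome and oxidative phosphorylation lists shifted upward, with 14 of 33 and 16 of 51 genes higher, but both calls were lost at adjusted p = 0.0926 and 0.155 with an estimated correlation. The remaining genes of the 10 largest increases were the deubiquitinase Usp8 (1.10 ± 0.52), the actin-binding protein Dbn1 (1.09 ± 0.36), the transcription factor Prdm16 (1.00 ± 0.22), Sephs1 (0.96 ± 0.24) and the exosome subunit Exosc9 (0.96 ± 0.35). The remaining decreases were Shisa5 (-1.04 ± 0.30, n = 7), Igfbp3 (-0.94 ± 0.24, n = 7), which binds insulin-like growth factors, the antiproliferative gene Btg1 (-0.90 ± 0.40) and the extracellular chaperone Clu (-0.89 ± 0.43), together with Nfkbia (-0.87 ± 0.30), Mfge8 (-0.80 ± 0.41), Lsp1 (-0.74 ± 0.39) of leukocytes and the chemokine Cxcl12 (-0.70 ± 0.31). Adjusted p for these 20 genes lay between 3.66e-07 for Xist and 0.000897 for Lcn2.

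Of the 45 cell cycle and DNA replication genes, 37 rose, 0 fell and 8 did not pass, with 38 adjusted over the list alone (median 0.57, adjusted p = 2.11e-37, and 0.00615 with an estimated correlation). Pcna (0.85 ± 0.26), the sliding clamp of DNA polymerase, Mki67 (0.82 ± 0.20), Birc5 (0.81 ± 0.20), also known as survivin, and the tubulin regulator Stmn1 (0.81 ± 0.49) rose the most. Stmn1 read 1.16 to 1.49 on replicates 3, 5 and 7 but 0.208 to 0.362 on replicates 2, 6 and 8. Of the 15 genes of globins and haem synthesis, 12 rose, 0 fell and 3 did not pass, with 12 adjusted over the list alone (median 0.55, adjusted p = 2.33e-22, and 0.00615 with an estimated correlation). Besides Alas2 and Alad these held Tmem14c (0.81 ± 0.26), a mitochondrial carrier of haem precursors, and the embryonic beta-like globin Hbb-y (0.92 ± 0.26), whose cDNA spots may also bind near-identical globins, so that its identity is uncertain. Hba-a1 (0.040 ± 0.16) did not pass (adjusted p = 0.686). Of the 15 red cell enzymes and antioxidants, 12 rose, 0 fell and 3 did not pass, with 13 adjusted over the list alone (median 0.47, adjusted p = 9.06e-13, and 0.00615 with an estimated correlation). Glrx5 (0.89 ± 0.25), a glutaredoxin of iron-sulphur cluster assembly, Bpgm (0.86 ± 0.40), Mgst3 (0.85 ± 0.16) and Car1 (0.77 ± 0.24) led them. Of the 8 red cell membrane genes, 4 rose, 0 fell and 4 did not pass, with 5 adjusted over the list alone (median 0.50, adjusted p = 1.39e-07, and 0.0236 with an estimated correlation). The 4 were Slc4a1, Rhd (0.83 ± 0.47), Cd24a (0.77 ± 0.36) and Bsg (0.72 ± 0.21). Of the 7 erythroid regulators, Tfrc (0.64 ± 0.20), Bnip3l (0.60 ± 0.16) and Foxo3 (0.43 ± 0.25) rose, 0 fell and 4 did not pass, with 3 adjusted over the list alone (median 0.084, adjusted p = 0.000345, but adjusted p = 0.0833 with an estimated correlation).

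Of the 51 oxidative phosphorylation genes, 16 rose, 1 fell and 34 did not pass in AcB61, with 18 higher and 1 lower when adjusted over the list alone (median 0.17, adjusted p = 5.28e-06, but adjusted p = 0.155 with an estimated correlation). Ndufs6 (0.81 ± 0.27) and Ndufb9 (0.47 ± 0.19) of complex I and Atp5b (0.45 ± 0.11) and Atp5md (0.45 ± 0.56) of the ATP synthase rose the most. The list mean was 0.257, 0.311 and 0.264 on replicates 2, 6 and 8 and 0.062 to 0.188 on the other AcB61 arrays. Of the 33 proteasome genes, 14 rose, 1 fell and 18 did not pass, with 19 higher and 1 lower when adjusted over the list alone (median 0.16, adjusted p = 9.08e-05, but adjusted p = 0.0926 with an estimated correlation). Psmb7 (0.32 ± 0.33), Psmd1 (0.32 ± 0.13) and Psme3ip1 (0.30 ± 0.35), which binds a proteasome activator and is no subunit, rose and Psme1 (-0.36 ± 0.40) fell. Psme1 read -1.06 to -0.583 on replicates 2, 6 and 8 but -0.0919 to 0.0462 on replicates 3, 5 and 7. Of the 23 chaperones, 7 rose, 2 fell and 14 did not pass, with 10 higher and 3 lower when adjusted over the list alone (median 0.094, adjusted p = 0.000908, but adjusted p = 0.0691 with an estimated correlation). Hsp90aa1 (0.59 ± 0.13), Hspe1 (0.31 ± 0.27) and Tcp1 (0.30 ± 0.10) rose, and Hsp90b1 (-0.33 ± 0.35) of the endoplasmic reticulum fell. Hsp90b1 read -0.80 to -0.62 on replicates 2, 6 and 8 but -0.00417 to 0.0648 on replicates 3, 5 and 7. Of the 15 genes of stroma, vessels and fat, 9 fell, 1 rose and 5 did not pass, with 10 lower and 1 higher when adjusted over the list alone (median -0.21, adjusted p = 0.00376, but adjusted p = 0.0841 with an estimated correlation). Bgn (-0.57 ± 0.36, n = 7), Timp3 (-0.43 ± 0.34) and Pecam1 (-0.35 ± 0.22) fell, and the collagen gene Col3a1 (0.43 ± 0.077) rose. Of the 13 macrophage genes, 4 fell, 2 rose and 7 did not pass, with 8 lower and 2 higher when adjusted over the list alone (median -0.20, adjusted p = 0.0357, but adjusted p = 0.218 with an estimated correlation). Axl (-0.37 ± 0.21, n = 7), a receptor for dying cells, and C1qb (-0.35 ± 0.23) fell, and the proteases Ctsb (0.34 ± 0.32) and Ctsd (0.28 ± 0.32) rose. This shift was no longer past the threshold without AcB61 replicate 2, 6 or 8 (adjusted p = 0.0659, 0.0671 and 0.0887). Of the 7 interferon response genes, 3 fell, 0 rose and 4 did not pass, with 4 adjusted over the list alone (median -0.19, adjusted p = 0.0275, but adjusted p = 0.218 with an estimated correlation). They were Igtp (-0.48 ± 0.28), Irf1 (-0.45 ± 0.25, n = 7) and Ifitm3 (-0.30 ± 0.30).

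The 61 cytosolic ribosomal protein genes did not shift in AcB61 (median -0.021, adjusted p = 0.867). Rps2 (0.28 ± 0.15, n = 7) and Rplp0 (0.20 ± 0.19) rose, Rpl5 (-0.16 ± 0.15) fell and 58 did not pass, with 1 higher and 0 lower when adjusted over the list alone. Of 8 iron handling genes, 3 rose, 0 fell and 5 did not pass, as when adjusted over the list alone (adjusted p = 0.114, but 0.0268 with every probe its own feature, and 0.167 with an estimated correlation). The 3 were Lcn2 and the ferritin chains Fth1 (0.25 ± 0.22) and Ftl1 (0.17 ± 0.065). Hmox1 (0.093 ± 0.26) did not pass (adjusted p = 0.492). Of 11 glycolysis genes, 3 rose, 1 fell and 7 did not pass, with 4 higher and 1 lower when adjusted over the list alone (adjusted p = 0.245). The hexokinase Hk1 (0.53 ± 0.28), Pfkm (0.34 ± 0.22) and Gapdh (0.23 ± 0.10) rose and Pkm (-0.33 ± 0.31) fell. Pkm read -0.737 to -0.612 on replicates 2, 6 and 8 but -0.115 to 0.0232 on replicates 3, 5 and 7. Of the short lists, those of MHC class II and class I had 1 of 2 and 3 of 4 genes lower (adjusted p = 0.0012 and 0.00707, but adjusted p = 0.0842 and 0.0578 with an estimated correlation). The MHC class I genes H2-K1 (-0.51 ± 0.34) and Tap2 (-0.22 ± 0.17), the platelet genes Ppbp (-0.63 ± 0.48) and Selp (-0.22 ± 0.22), Xbp1 (-0.49 ± 0.34), the costimulatory ligand Icosl (-0.37 ± 0.20) and the histidine decarboxylase Hdc (-0.29 ± 0.20) fell. Satb1 (-0.025 ± 0.12) and Cpa1 (-0.27 ± 0.46) did not pass.

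In total 3103 features passed the test in AcB61, 1365 higher and 1738 lower, of which 836 and 553 were named genes. At least 1.5-fold changes were 255 of them. The list means of the cell cycle, haem synthesis, red cell enzymes, proteasome and oxidative phosphorylation had a single sign on all 8 arrays (exact two-sided sign-flip p = 0.00781, the smallest that 8 arrays allow, and 0.00965 adjusted over the lists). Calls were lost for Atp5md without AcB61 replicate 3, 4, 5 or 7 (adjusted p = 0.0639, 0.0594, 0.0701 and 0.0688), for Ctsd without 3, 5 or 7 (0.0616, 0.0585 and 0.0644), and for Psme1 without 6 or 8 (0.051 and 0.0559). They were also lost for Psme3ip1 without 2, 6 or 8 (0.064, 0.066 and 0.0719) and for Rpl5 without 1, 2, 4, 5, 7 or 8 (0.0555, 0.0831, 0.0673, 0.0739, 0.0686 and 0.108). In a fit of the AcB61 arrays alone, that of Selp was lost as well (0.0508).

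The third comparison set the strains against each other through the shared A/J channel and tested AcB61 minus AcB55. The cytosolic ribosomal protein, oxidative phosphorylation and proteasome lists were shifted upward in AcB61, with 28 of 61, 9 of 51 and 1 of 33 genes higher. All 3 calls were lost with an estimated correlation (adjusted p = 0.125, 0.446 and 0.499). The lists of the cell cycle and of red cell precursors did not pass the same test, which sets a list against all other tested features. Of called features without a single gene name 27.8% were higher in AcB61, against 65.2% of called named genes. This lean may push lists of named genes upward in the test, and its part was not separated. Cpt2 (1.36 ± 0.084) and Nemp1 (1.19 ± 0.11) differed the most upward, since they were low in AcB55 and near A/J in AcB61, and Xist (-1.22 ± 0.14) and Prex2 (-1.26 ± 0.21) the most downward. Mki67 (-1.01 ± 0.11) was higher in AcB55. Values in this paragraph and the next are differences of mean log2 ratios ± SE, over 6 AcB55 and 8 AcB61 arrays. The other 10 largest positive differences were Olfml3 (1.18 ± 0.14), Mtpn (1.08 ± 0.12), Lhpp (1.04 ± 0.084), Hrct1 (0.96 ± 0.100), Gemin2 (0.89 ± 0.081), which acts in the assembly of spliceosomal particles, the angiotensin receptor Agtr2 (0.89 ± 0.12), Cluap1 (0.89 ± 0.13) and Mael (0.88 ± 0.11). The other 10 largest negative differences were Odf2 (-1.10 ± 0.16), Ap3d1 (-1.04 ± 0.24), the signalling kinase Irak1 (-0.96 ± 0.17), Mrps25 (-0.92 ± 0.17) of the mitochondrial ribosome, Slc4a2 (-0.91 ± 0.14), butyrylcholinesterase Bche (-0.84 ± 0.15) and the GTPase Igtp (-0.81 ± 0.12). Prex2, Odf2, Irak1, Bche and Ap3d1 read highest on AcB55 replicates 3 and 4, the arrays marked b. Log2 ratios to A/J there were 1.88 and 1.92 for Prex2, against 0.59 to 1.02 on the other AcB55 arrays that measured it. For Ap3d1 they were 1.03 and 1.92, against -0.206 to 0.853 on the others. The sizes of these differences thus rest in part on those 2 arrays. Adjusted p for these 20 genes lay between 5.23e-08 for Cpt2 and 0.00984 for Ap3d1. The ranges of the strains did not overlap for any of them, which the rule for named genes required.

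Of the 61 cytosolic ribosomal protein genes, 28 were higher in AcB61, 0 lower and 33 did not pass, with 44 higher and 1 lower when adjusted over the list alone (median 0.29, adjusted p = 2.3e-15, but adjusted p = 0.125 with an estimated correlation). Rpl38 (0.65 ± 0.13), Rpl13a (0.65 ± 0.12), Rps14 (0.62 ± 0.11) and Rpl36 (0.57 ± 0.14) differed the most. An exact permutation test of the list means per array over all 3003 splits gave a p of 0.000333 (0.00699 adjusted over the lists). Of the 51 oxidative phosphorylation genes, 9 were higher, 0 lower and 42 did not pass, with 22 adjusted over the list alone (median 0.29, adjusted p = 2.48e-09, but adjusted p = 0.446 with an estimated correlation, and exact permutation p = 0.00167, adjusted 0.0175). Ndufs6 (0.83 ± 0.12), Cox6b1 (0.56 ± 0.14), Ndufb9 (0.46 ± 0.12) and Ndufa7 (0.36 ± 0.095) were the largest. Of the 33 proteasome genes, Psmb4 (0.30 ± 0.089) was higher, 0 were lower and 32 did not pass, with 0 adjusted over the list alone (median 0.20, adjusted p = 0.00268, but adjusted p = 0.499 with an estimated correlation, and exact permutation p = 0.00366, adjusted 0.0192). Globins and haem synthesis (adjusted p = 0.198) held Hbb-y (0.85 ± 0.12), Alas2 (0.51 ± 0.13) and Tmem14c (0.39 ± 0.12), which were higher in AcB61. The size given for Hbb-y is not reliable, since on 4 of 6 AcB55 arrays its spots read within 0.025 of those of Hba-a1, which look saturated. Red cell enzymes (adjusted p = 0.213) held Txn1 (0.56 ± 0.17) and Glrx5 (0.45 ± 0.14), which were higher, and Cat (-0.48 ± 0.15), which was lower. The log2 ratio of Cat to A/J was 0.667 to 0.873 on AcB61 replicates 2, 6 and 8, within its AcB55 range of 0.599 to 0.881. On the other AcB61 arrays it was -0.0272 to 0.104. Without AcB55 replicates 1 and 2, chosen after the data were seen, the haem synthesis and red cell enzyme lists were past the threshold (adjusted p = 0.00975 and 0.0229). With an estimated correlation over all 14 arrays they were not (0.499 and 0.566). The haem synthesis list was also past the threshold in settings fixed beforehand, with every probe its own feature (adjusted p = 0.00089) and without AcB55 replicate 1 alone (0.0368). The former counts the 7 spots of Hba-a1 and the 4 of Hbb-y singly, which are not reliable. The fry test asks whether a list changed at all rather than more than other features, and it gave adjusted p = 0.0464 for haem synthesis and 0.0113 for the red cell membrane list. In the red cell membrane list Cd24a (0.71 ± 0.14) and Ermap (0.25 ± 0.076) were higher, and among erythroid regulators Bcl2l1 (-0.76 ± 0.20) was lower. Tfrc (-0.030 ± 0.10) did not differ over its pair of probes, which were called in opposite directions. In the cell cycle list Cks1b (0.73 ± 0.12) and Cenpa (0.36 ± 0.077) were higher and Mcm3 (-0.41 ± 0.10) lower, besides Mki67. Hmox1 (-0.79 ± 0.13) was lower in AcB61. Outside the ribosomal protein, oxidative phosphorylation and proteasome lists, adjusted p of lists with at least 5 measured genes lay between 0.198 for globins and haem synthesis and 0.721 for stroma, vessels and fat. Hba-a1 (0.053 ± 0.086) did not pass (adjusted p = 0.734). Blnk (0.49 ± 0.13), Xbp1 (0.52 ± 0.16), Il18 (0.38 ± 0.100), Bst2 (0.52 ± 0.11) and Stat2 (0.27 ± 0.059) were higher, and H2-K1 (-0.70 ± 0.14) and H2-DMa (-0.33 ± 0.082) lower. Col3a1 (0.57 ± 0.060), Calr (0.31 ± 0.088) and Cct5 (0.33 ± 0.095) were higher and Timp3 (-0.45 ± 0.13), Col4a1 (-0.24 ± 0.072) and Hspa8 (-0.28 ± 0.074) lower.

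In total 1601 features differed between the strains, 690 higher and 911 lower in AcB61, of which 427 and 228 were named genes. Calls were lost without AcB55 replicate 6 for Alas2, Blnk, Calr, Cat, Cct5, Col4a1, Ermap, Glrx5, Ndufa7, Psmb4, Timp3, Tmem14c, Txn1 and Xbp1 (adjusted p from 0.058 for Alas2 to 0.132 for Tmem14c). They were lost without replicate 4 for Bcl2l1 and Hspa8 (0.0525 and 0.0612) and without replicate 5 for Il18 (0.0631), and other single arrays also ended some of these calls. Of 14 fits that each left out 1 array, 10 lost the call of Cat, 9 those of Ermap and of Col4a1, and 8 that of Glrx5. For Calr and Cct5 it was 5 fits each. Without the 2 arrays marked b those of Rpl36, Cox6b1 and Ndufb9 were lost as well (0.0851, 0.0696 and 0.106), and without AcB55 replicates 1 and 2 that of Mcm3 (0.0681). The count fell to 854 without AcB55 replicate 6, 924 without replicate 5 and 705 without the 2 arrays marked b.

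**Figure D2:**
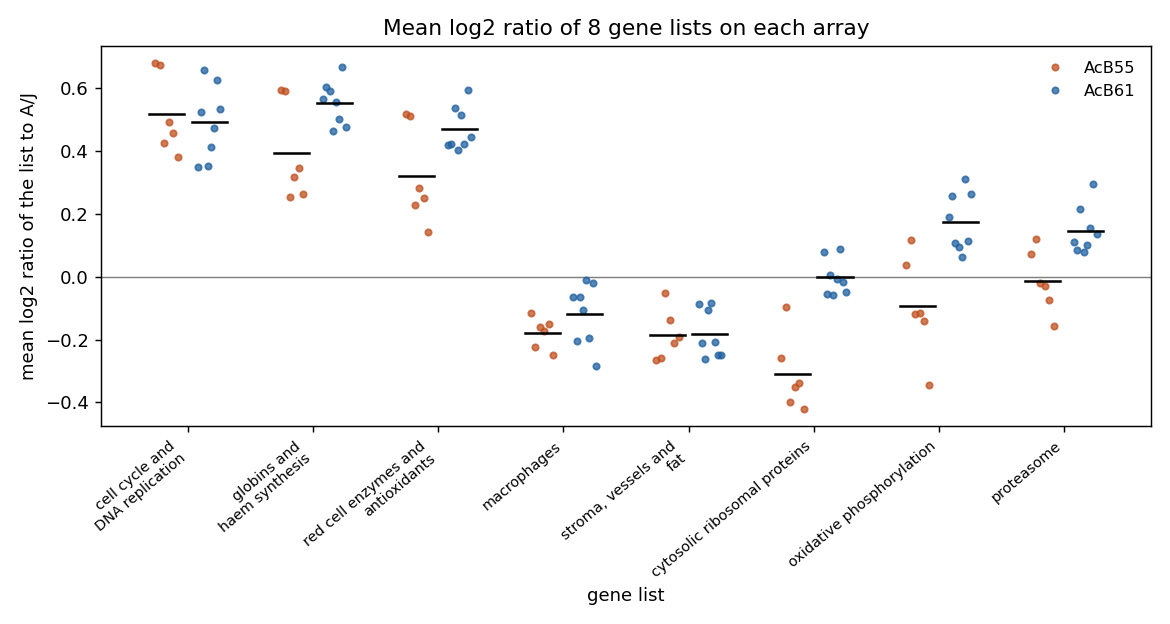
Mean log2 ratio to A/J of the measured genes of 8 lists (vertical axis) on each array, with AcB55 in orange, AcB61 in blue, a point per array and a black bar at the mean of each strain. The cell cycle, haem synthesis and red cell enzyme lists lie above 0 on all 14 arrays, and the ribosomal protein list lies at -0.42 to -0.097 in AcB55 and at -0.057 to 0.088 in AcB61.

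A last comparison counted genes that changed the same way in both strains. Higher in both were 509 features, 355 of them named genes, and lower in both were 404, 295 of them named genes. Named genes at least 1.5-fold higher in both numbered 44, with Slc4a1, Rhd, Mki67, Bpgm and Tfrc among them, and those at least 1.5-fold lower in both numbered 16, with H2-Eb1, Shisa5, Nfkbia and B2m. The strains did not differ past the threshold for 810 of these 913 features and did for 103. Opposite directions were seen for 103 features, 86 of them higher in AcB55 and lower in AcB61. Of these, 29 were named genes, among them Igtp (0.33 in AcB55 and -0.48 in AcB61), Cks1b (-0.44 and 0.30) and Col3a1 (-0.14 and 0.43). Independent lists of these sizes would share 133 higher and 189 lower features and oppose in 318. The mean log2 ratios correlated across features at r = 0.417 with a covariance of 0.0173, where features are not independent replicates. In a simulation with no strain effect, 1 A/J sample shared by all arrays gave 3260 features in the same direction, r = 0.871 and a covariance of 0.041, and no shared sample gave 0, r = 0.00051 and 2.94e-06. With the shared sample, whose spread was set equal to that between arrays, 4180 features were called in AcB55 and 5210 in AcB61. The simulated counts of calls and of shared features, r and covariance with that sample all exceed the real ones, and the true spread among A/J samples is unknown, so part or all of the overlap may come from the shared control. The arrays could not be split by A/J sample. Without AcB55 replicates 1 and 2, chosen after the data were seen, the count of 913 fell to 591.

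**Figure D3:**
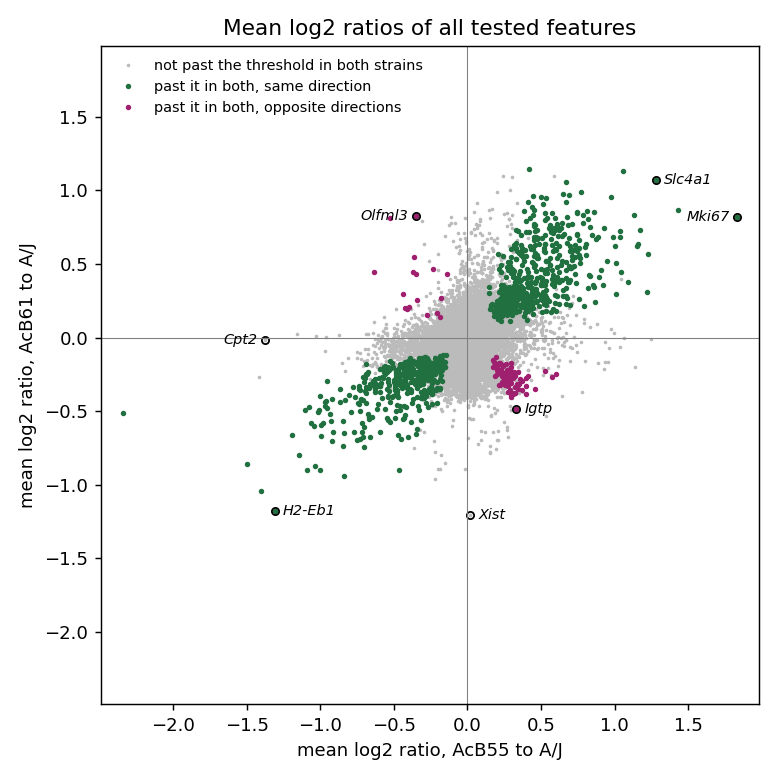
Mean log2 ratio to A/J in AcB55 (horizontal axis, 6 arrays) against AcB61 (vertical axis, 8 arrays), with a point for each of 13045 tested features. Green points passed the test in both strains in the same direction (913), magenta points in opposite directions (103), grey points are all others, and circles mark named genes.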

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

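The counts against sign patterns and splits of the arrays were planned, whereas the tests on the spread of the AcB61 arrays and on Hba-a1 were chosen after those results were seen. Of the 32 sign patterns of the AcB55 arrays, 1 gave as many called features as the real one, the real one itself, with 2695 against at most 401 in the others. Of 100 sign patterns drawn for AcB61, 1 did so, with 3103 against at most 1896. Of 100 splits drawn of the 14 arrays into 6 and 8, 1 gave as many as the real split, with 1601 against at most 0. If the arrays are independent, how single arrays fall by chance does not account for these 3 counts. Arrays may share a mouse or an RNA pool, so chance differences between mice or pools are not excluded for any of them. Signs flipped per array also cannot show a chance value of an A/J sample that arrays share. A simulation with such a sample shared by all 14 arrays and no strain effect gave 4180 calls in AcB55 and 5210 in AcB61. For both counts against A/J a chance value of the A/J sample is thus not excluded. Its 0 calls between the strains decide nothing on A/J, since a sample shared by all arrays cancels in that difference. Different A/J samples for each strain were not simulated, so the count between the strains is not cleared of such chance. Arrays with like leading digits in their numbers all hold 1 strain, so an effect of such a series on the count between the strains cannot be told apart from the strain. The 1896 calls under another sign pattern point to a structure among the AcB61 arrays.

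The first component of the residuals held 43.6% of their variance and spread the AcB61 arrays along an axis. Scores were 0.355, 0.46 and 0.402 for replicates 2, 6 and 8, -0.386, -0.379 and -0.422 for replicates 3, 5 and 7, and 0.0543 and -0.0842 for replicates 1 and 4. Some genes named for AcB61 split along this axis, among them Hsp90b1, Pkm, Psme1 and Stmn1, so their strain means rest more on 1 side of it. The manufacturing series of the arrays, taken here from the leading digits of the array numbers in the titles and stated by no label, is argued against, since 22% of the variance of these scores lay between series and both series with 3 AcB61 arrays span both signs (-0.386 to 0.355 and -0.422 to 0.46). An effect of single spots, such as labelling or dye, is a candidate explanation: the loadings of 2 probes of a gene correlated at 0.0781 (bootstrap interval 0.00466 to 0.152), whereas the strain means of the same 850 genes correlated at 0.459 and 0.461. The first component of the AcB55 arrays alone gave 0.189 (0.109 to 0.272), an interval that overlaps the former. Low agreement between probes is thus not particular to the AcB61 axis. A different cell content of the spleens stays open, because 1 of the 6 lists tested for it (macrophages, stroma, red cell membrane, erythroid regulators, haem synthesis and cell cycle) had a shifted loading, macrophages (median -1.29, adjusted p = 0.0014), and outside these 6 so did red cell enzymes (-0.796, adjusted p = 0.0168) and oxidative phosphorylation (1.23, adjusted p = 0.0014).

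Hba-a1 read near 0 in both strains while haem synthesis genes rose. Its 7 spots differed on an array by a median SD of 0.0018, against a median of 0.164 over the 250 genes with at least 3 probes, of which the next lowest had 0.0466. Both channels at the ceiling of the scanner on these spots may give such values, and equal adult alpha globin RNA in the strains and A/J cannot be told apart from it, because 0 percent of the other genes had a smaller SD and a saturated spot shows no difference. The 4 spots of Hbb-y had a median SD of 0.0144 in AcB55 and 0.117 in AcB61, and they read within 0.025 of Hba-a1 on AcB55 replicates 3 to 6. The AcB55 values of Hbb-y may thus lie at the same ceiling, and the size of its difference between the strains (0.85) is not reliable.

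Tested differences between the strains, as AcB61 minus AcB55, are listed here as values. The limits given above hold for them, such as for Cat, whose call was lost in 10 of 14 fits without a single array. The list medians of cytosolic ribosomal proteins, proteasome and oxidative phosphorylation differed by 0.29, 0.20 and 0.29, and all 3 calls were lost with an estimated correlation (adjusted p = 0.125, 0.499 and 0.446). Genes higher in AcB61 were Cpt2 (1.36), Nemp1 (1.19), Olfml3 (1.18), Mtpn (1.08), Lhpp (1.04), Hrct1 (0.96), Gemin2 (0.89), Agtr2 (0.89), Cluap1 (0.89), Mael (0.88), Hbb-y (0.85, with the limit above), Ndufs6 (0.83) and Cks1b (0.73). Smaller positive differences were those of Cd24a (0.71), Rpl38 (0.65), Rpl13a (0.65), Rps14 (0.62), Rpl36 (0.57), Col3a1 (0.57), Cox6b1 (0.56), Txn1 (0.56) and Bst2 (0.52). Still smaller ones were those of Xbp1 (0.52), Alas2 (0.51), Blnk (0.49), Ndufb9 (0.46), Glrx5 (0.45), Tmem14c (0.39), Il18 (0.38), Ndufa7 (0.36), Cenpa (0.36), Cct5 (0.33), Calr (0.31), Psmb4 (0.30), Stat2 (0.27) and Ermap (0.25). Genes lower in AcB61 were Prex2 (-1.26), Xist (-1.22), Odf2 (-1.10), Ap3d1 (-1.04), Mki67 (-1.01), Irak1 (-0.96), Mrps25 (-0.92), Slc4a2 (-0.91), Bche (-0.84), Igtp (-0.81) and Hmox1 (-0.79). Smaller negative differences were those of Bcl2l1 (-0.76), H2-K1 (-0.70), Cat (-0.48), Timp3 (-0.45), Mcm3 (-0.41), H2-DMa (-0.33), Hspa8 (-0.28) and Col4a1 (-0.24).

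Single arrays stood far from the others of their strain in 12 of 330 groups of values (3.64%), where chance gives about 1 in 20. In AcB55, replicate 1 stood apart for Ermap (-0.48) and Rplp0 (0.081), replicate 2 for Ndufa7 (-0.012), Rpl38 (-0.149), Rps13 (-0.35) and Timp3 (0.265), replicate 5 for Cat (0.60) and replicate 6 for the mean of the chaperone list (-0.069). In AcB61, replicate 4 stood apart for Ap3d1 (-0.82), replicate 1 for Col3a1 (0.60), replicate 3 for Satb1 (0.22) and replicate 5 for the number of features with a value (14197).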

How the results depend on the processing

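The first residual component as covariate and the fit without the 2 AcB55 arrays highest in S100a9 were chosen after seeing the data, and the other alternatives were planned. No result reversed. Of the values of single named genes under alternatives, 5200 kept their side of the threshold and 178 fell short of it. Many of these alternatives left out 1 array or hardly changed the values. For a call against A/J, leaving out an array of the other strain leaves the mean as it was. The tally is thus no measure of robustness. The count for AcB61 against AcB55 (1601) became 2584 with array series as a random block. Each series holds 1 strain, so the block cannot adjust this comparison, and its estimated correlation was negative (-0.139). The count became 705 without the 2 arrays marked b, 2826 with array weights and 3571 with the first residual component as covariate. That component was taken from the residuals of the same fit. As a covariate it removes residual spread by construction, so the higher counts with it lend no support. With single arrays left out the count ranged from 854 to 1694. Features changed in both strains (913) became 1535 with the residual component as covariate, with the same limit, and 591 without the 2 AcB55 arrays highest in S100a9. With at least a 1.5-fold change, a stricter rule by construction, the counts were 330, 255 and 240. Called lists numbered 12, 14 and 3 in the 3 comparisons, which includes lists with fewer than 5 genes, B cells and plasma cells in AcB55 and B cells, MHC class II and MHC class I in AcB61. Those of AcB55 became 7 with features on all 14 arrays and 4 with an estimated correlation, and those of AcB61 4 with an estimated correlation. Those between strains became 0 with an estimated correlation, 8 with fry, which tests against no change, 6 without the 2 AcB55 arrays highest in S100a9, and 3 to 5 with single arrays left out. The B cell list has no estimated correlation. With features on all 14 arrays, the lists of the red cell membrane, interferon response and oxidative phosphorylation lost their calls in AcB55 (adjusted p = 0.0921, 0.149 and 0.0921), as did plasma cells and B cells, the last with no gene left, and macrophages and interferon response theirs in AcB61 (0.073 each). With array weights, macrophages and interferon response in AcB61 also lost theirs (0.0649 and 0.0877), and the called lists there fell to 11, the remaining loss being among lists with fewer than 5 genes. With the first residual component as covariate, interferon response in AcB55 lost its call (0.0551). In AcB55 the chaperone list passed without AcB55 replicate 6 (0.0294) and with every probe its own feature (0.00466), and iron handling passed without AcB55 replicate 5 or 6 or AcB61 replicate 2 (0.0483, 0.0357 and 0.0448). In AcB61 iron handling passed with every probe its own feature (0.0268). With an estimated correlation the chaperone and iron handling lists did not pass in AcB55 (adjusted p = 0.454 and 0.537), nor did iron handling in AcB61 (0.167). Apart from the smaller numbers of arrays, the stricter rule and the counts with the residual component, the cause was not tested. No value lay beyond 5 on the log2 scale, so capping values was not run. No paired analysis was possible because replicate numbers were given in accession order and pair no samples. Signal over background was not analysed here, so its limit on weak spots is unknown.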

Other observations

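Genes in this part were chosen after their values were seen, whereas the test of neighbouring genes was planned. Several genes outside the lists changed at least 1.5-fold in both strains. Higher were Odc1, which makes polyamines (0.74 and 0.59), and Azin1, which protects that enzyme (0.80 and 0.61), the histone chaperone Asf1b (0.73 and 0.60), Fbxo5, an inhibitor of the anaphase-promoting complex (0.73 and 0.63), and Ube2o, which ubiquitinates proteins in reticulocytes (0.86 and 0.85). Lower were Flna, an actin crosslinker (-0.59 and -0.64), Arpc1b of the Arp2/3 complex (-0.99 and -0.60), the integrin Itgb7 of lymphocytes (-0.71 and -0.64) and Zfp36, which destabilises cytokine mRNAs (-0.66 and -0.67). The values in parentheses are mean log2 ratios in AcB55 and in AcB61.

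Genes that changed in opposite directions included some of cell division. Pttg1, which encodes securin, was 0.52 ± 0.20 in AcB55 and -0.23 ± 0.14 in AcB61, and the centriole protein Stil was 0.21 ± 0.17 and -0.23 ± 0.12, whereas the kinase subunit Cks1b was -0.44 ± 0.19 and 0.30 ± 0.28. The inflammasome adaptor Pycard was 0.29 ± 0.11 and -0.18 ± 0.18, the purine enzyme Pnp -0.34 ± 0.14 and 0.25 ± 0.26, and Igtp 0.33 ± 0.15 and -0.48 ± 0.28. Each pair differed in the test between the strains, with adjusted p from 0.000108 for Pttg1 to 0.00265 for Pnp. This adds no separate support, since genes called in opposite directions in the same fit are very likely to pass it.

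Xist lay between -0.075 and 0.081 on the AcB55 arrays and between -1.71 and -0.73 on the AcB61 arrays. Whether the sexes of the AcB61 and A/J mice were matched is not given. Of other X-linked genes, Eif2s3x was 0.53 ± 0.16 in AcB55 (adjusted p = 5.76e-05) and 0.25 ± 0.21 in AcB61 (adjusted p = 0.0101), Kdm5c 0.34 ± 0.23 and 0.085 ± 0.20, Kdm6a 0.28 ± 0.097 and 0.071 ± 0.31, and Ddx3x -0.024 ± 0.21 and -0.028 ± 0.19. Cpa1, a digestive enzyme of the pancreas, ranged from -3.58 to 2.37 over the 5 AcB55 arrays that measured it and from -0.89 to 0.48 in AcB61. Called features without a single gene name leaned the other way from named genes: 56.1% of 1014 were higher in AcB55 against 41.9% of 1681 named genes, 30.9% of 1714 against 60.2% of 1389 in AcB61, and 27.8% of 946 against 65.2% of 655 between the strains. The list tests set named genes against all tested features. This lean may thus push lists downward in AcB55 and upward in AcB61 and between the strains, which was not tested. Up to 20 features shared a single value on AcB55 replicate 6 (-0.080).

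One hypothesis was that genes differing between the strains cluster on chromosomes, because neighbouring genes on one chromosome share inherited segments that differ between the strains. Of 653 called genes with a known place, 19.9% had a called neighbour among the measured genes, against a median of 19.6% and a central range of 15.6% to 23.7% in 10000 random draws, so the test was negative. The longest run of called neighbours had 4 genes, Fam234a, Atp6v0e, Crebrf and Bnip1 on chromosome 17, all higher in AcB61.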
